A study of Synechocystis sp. PCC 6803 with 12 samples.

How the data were processed

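RNA of Synechocystis sp. PCC 6803 was measured on 12 one-colour arrays of a custom design, 2 for each of 6 groups (WT and the mutant without SbtB, at 0 h, 3 h and 24 h). Per the labels' protocols, RNA was treated with DNase and labelled with Cy3 in 2 µg aliquots without cDNA synthesis, and the series' design text calls the replicates biological. The groups were taken from the sample titles. The carbon words of the sample labels conflict with the treatment protocol and were not used to form groups.

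Per the file headers, the deposited intensity values were extracted with Agilent Feature Extraction 10.7.3.1, whose processed signal is corrected for background and spatial trend and raised to a floor where it is too dim. Taking each array's most common signal as the floor, 24.2% to 43.3% of the probes held exactly this value on 10 arrays. On replicate 2 of WT and of the mutant at 3 h only 0.00492% did. Undetected probes there had close but unequal signals, so this share does not count the probes raised to a floor on these arrays. Why these arrays differ is not given in the sources used here. The deposited value table holds log2 values. Set against the scanner files, each of its columns was a smooth rising function of the log2 median spot signal of the same array. The rank correlation was 1, so no background was subtracted spot by spot. A background correction common to all spots of an array would keep the ranks and cannot be excluded. Its column medians ranged from 9.53 to 9.98, so the arrays were not made equal by quantiles, and how the authors scaled it is not given in the sources used here. The submitters' processing notes name limma without a version. The flags of the scanner software were used as deposited.

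In this work, log2 of the processed signal was taken and each array's 75th percentile over its 61015 non-control probes was subtracted. Each such probe has 1 spot, so no averaging was needed. The 1319 control spots were left out, as were 9 probes with a spot marked as an outlier on any array. Probes well above background on at least 2 arrays were kept, which left 36778, of which 17384 were well above background on all 12 arrays. All 12 arrays entered 1 limma fit (version 3.58.1, R 4.3.3) with a mean for each of the 6 groups, 6 residual degrees of freedom and moderated variances (3.43 prior degrees of freedom). Probes were called at a Benjamini-Hochberg adjusted p under 0.05, and the number that also changed by at least 1 on the log2 scale was counted. Standard errors are those of the fit. The 10 comparisons were the mutant minus WT at each time and averaged over the times, 3 h and 24 h minus 0 h in each genotype, and the interaction at 3 h and at 24 h.

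The planned gene lists, the check of the deleted gene and the test of the carbon direction could not be run, because they are defined by locus tags and the files do not pair the serial probe names with genes. The table of gene names used here shares no identifier with the probes: 0 of the probe names matched. Averaging over the probes of a gene, or taking its brightest probe, was not possible for the same reason. In their place, the 5 probe series named in the files were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, adjusted over the 5 series of a comparison. The planned rule for naming features that are not protein-coding genes was the 3 largest rises and 3 largest falls, with adjusted p under 0.05 and, for comparisons of 2 groups, no overlap between the groups. That the CRISPR and leader probes would stand for these features was decided after the files were read. Single values of 2 probes that the rule selected are not reported here. The planned rules for protein-coding genes could not be applied. In their place, the 2 largest rises and 2 largest falls among the serial names in the average over the times were named, a choice also made after the files were read.

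Slide and scan were read from the scanner files. The 3 h arrays of both genotypes lay on 1 slide and the others on a second slide. A term for the slide could not be fitted beside the 6 groups, and the comparisons of genotypes are within a slide. Alternatives were normexp background correction (offset 50, on the median signal, since a mean signal column was not used here), quantile normalization, median scaling, the deposited value table, other filters on dim probes, a variance trend with robust estimation, only the arrays or the slide of the groups compared, the replicate number as a block, a larger threshold and leaving out each array. Scaling on the 75th percentile of the probes detected on all arrays was added after seeing the data, because several arrays detected a minority of their probes. Counting only calls on probes that an array of the groups compared detects was also added after seeing the data, because probes undetected in both groups were called where the floor of the processed signal differed between arrays after scaling.

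The fit was tested on simulated data for the comparison of the mutant with WT at 0 h, over 36778 probes with the observed means and spreads, of which 200 were changed. At a simulated log2 change of 0.5, 0 of 50 probes were recovered. At 1, 2 and 3, the fit recovered 24.0%, 94.0% and 100% of 50 probes each, and 2 unchanged probes were called. A difference of 1 on the log2 scale was therefore often below what 2 arrays per group could resolve when few probes change.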

Results

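Gene expression was measured in the cyanobacterium Synechocystis sp. PCC 6803, in a wild type (WT) and in a mutant that lacks SbtB, a PII-like signalling protein of the inorganic carbon response. Total RNA was labelled directly with Cy3 and hybridised to 12 one-colour arrays, 2 arrays for each genotype at each of 3 times titled 0 h, 3 h and 24 h. The labels give opposite accounts of the carbon supply. The treatment protocol describes a shift from air enriched with 5% CO2 to ambient air with 0.04% CO2, with sampling after 3 h and 24 h. The labels of the single samples call the 0 h arrays low carbon and the 3 h and 24 h arrays high carbon. The arrays are therefore named by their time alone, and no direction of the carbon supply is attached to any change. The labels also give a buffer of pH 8 for high carbon cultures and of pH 7 for low carbon cultures. Effects of carbon supply and of buffer pH cannot be told apart here.

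Each array carried 61015 non-control probes, each printed once. Of these, 60866 had only a serial name, and the files do not pair the serial names with genes. The files do name 142 probes of 3 CRISPR series and 7 probes of 2 leader series. CRISPR arrays are rows of short repeats and spacers whose transcripts are processed into guide RNAs against foreign DNA, and a leader is the sequence ahead of such a row that holds its promoter. What the number at the end of a CRISPR probe's name stands for is not given in the sources used here. A probe is called detected below where the scanner software marked it as well above background. The share of detected probes per array ranged from 34.0% to 54.7%. It averaged 51.3% ± 3.08 (SD, n = 6) on the WT arrays and 43.3% ± 5.71 (SD, n = 6) on the mutant arrays, and was lowest on the mutant arrays of 24 h, at 39.4% and 34.0%. No spot was saturated. On replicate 2 of both genotypes at 3 h, 0.00492% of probes held exactly the array's most common signal, against 24.2% to 43.3% on the other arrays. On these 2 arrays the share does not count the probes raised to a floor. Replicate arrays of a group correlated across probes with r between 0.964 and 0.982, and 2 arrays per group limit the precision of every value. Tests covered the 36778 probes detected on at least 2 arrays.

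The comparison of the mutant with WT asks what the loss of SbtB changes at each time. The clearest difference with a name lay in CRISPR1. Its probes numbered 15 to 42 were near background in WT and bright in the mutant, whereas its first probes had small median differences and went both ways at 24 h. Of the 28 probes numbered 15 to 42, 20 were detected on all 6 mutant arrays and 2 on all 6 WT arrays. Among the 25 of them tested, 21 were higher in the mutant at 0 h, 23 at 3 h and 24 at 24 h, and none was lower at any time. Leaving out calls on probes that no array of either group detected, 19, 22 and 24 were higher. The median log2 difference was 3.07 at 0 h, 4.11 at 3 h and 4.86 at 24 h. With signals below the detection limit raised to that limit, the medians were 1.75, 2.35 and 2.98. The 13 tested probes numbered 1 to 14 had medians of -0.79 at 0 h, -0.62 at 3 h and 0.01 at 24 h, and 7 of them were lower in the mutant at 0 h, 4 at 3 h and 4 at 24 h. None was higher at 0 h or 3 h, and 3 were higher at 24 h. These bounds of the numbering were set after the values were seen.

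Single CRISPR1 probes show the size of the difference. A fold against a group with no detected array is a lower bound. It sets the mean of the bright group against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal. The p-values printed beside such bounds belong to the fitted log2 differences against background signals and do not test the bounds. At 0 h and 24 h, R_CRISPR1-18, R_CRISPR1-22 and R_CRISPR1-25 had identical signals on each WT array. Their WT spread at these times is therefore that of the floor. R_CRISPR1-18 was at least 15.6-fold higher in the mutant at 0 h, 23.9-fold at 3 h and 63.8-fold at 24 h, detected on 6 of 6 mutant arrays and on 0 of 6 WT arrays (limma, adjusted p = 4.03e-07, 1.64e-07 and 1.16e-07). R_CRISPR1-25 was at least 5.91-fold higher at 0 h and 19.1-fold higher at 24 h (adjusted p = 7.31e-07 and 1.21e-07). R_CRISPR1-22 was at least 4.16-fold higher at 0 h and 16.8-fold higher at 24 h (adjusted p = 1.06e-06 and 1.21e-07). R_CRISPR1-27 was at least 8.90-fold higher at 3 h (adjusted p = 6.55e-06). At the other end of the series, R_CRISPR1-49 was detected on 6 of 6 WT arrays and 0 of 6 mutant arrays. It was at least 2.28-fold lower in the mutant at 0 h, 2.48-fold at 3 h and 3.12-fold at 24 h (adjusted p = 1.49e-05, 1.74e-05 and 6.78e-06). R_CRISPR1-9, detected on all arrays, had a log2 difference of -1.22 ± 0.15 (SE) at 0 h, -1.32 ± 0.15 at 3 h and -0.999 ± 0.15 at 24 h (adjusted p = 0.000323, 0.000385 and 0.000483). R_CRISPR1-6 was lower by a log2 difference of -1.41 ± 0.24 at 0 h (adjusted p = 0.00208). R_CRISPR1-48, detected on no mutant array, was at least 1.29-fold lower in the mutant at 3 h (adjusted p = 0.00533), but this call was lost with normexp background correction, in the deposited value table and without replicate 1 of WT at 3 h.

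**Figure D1:**
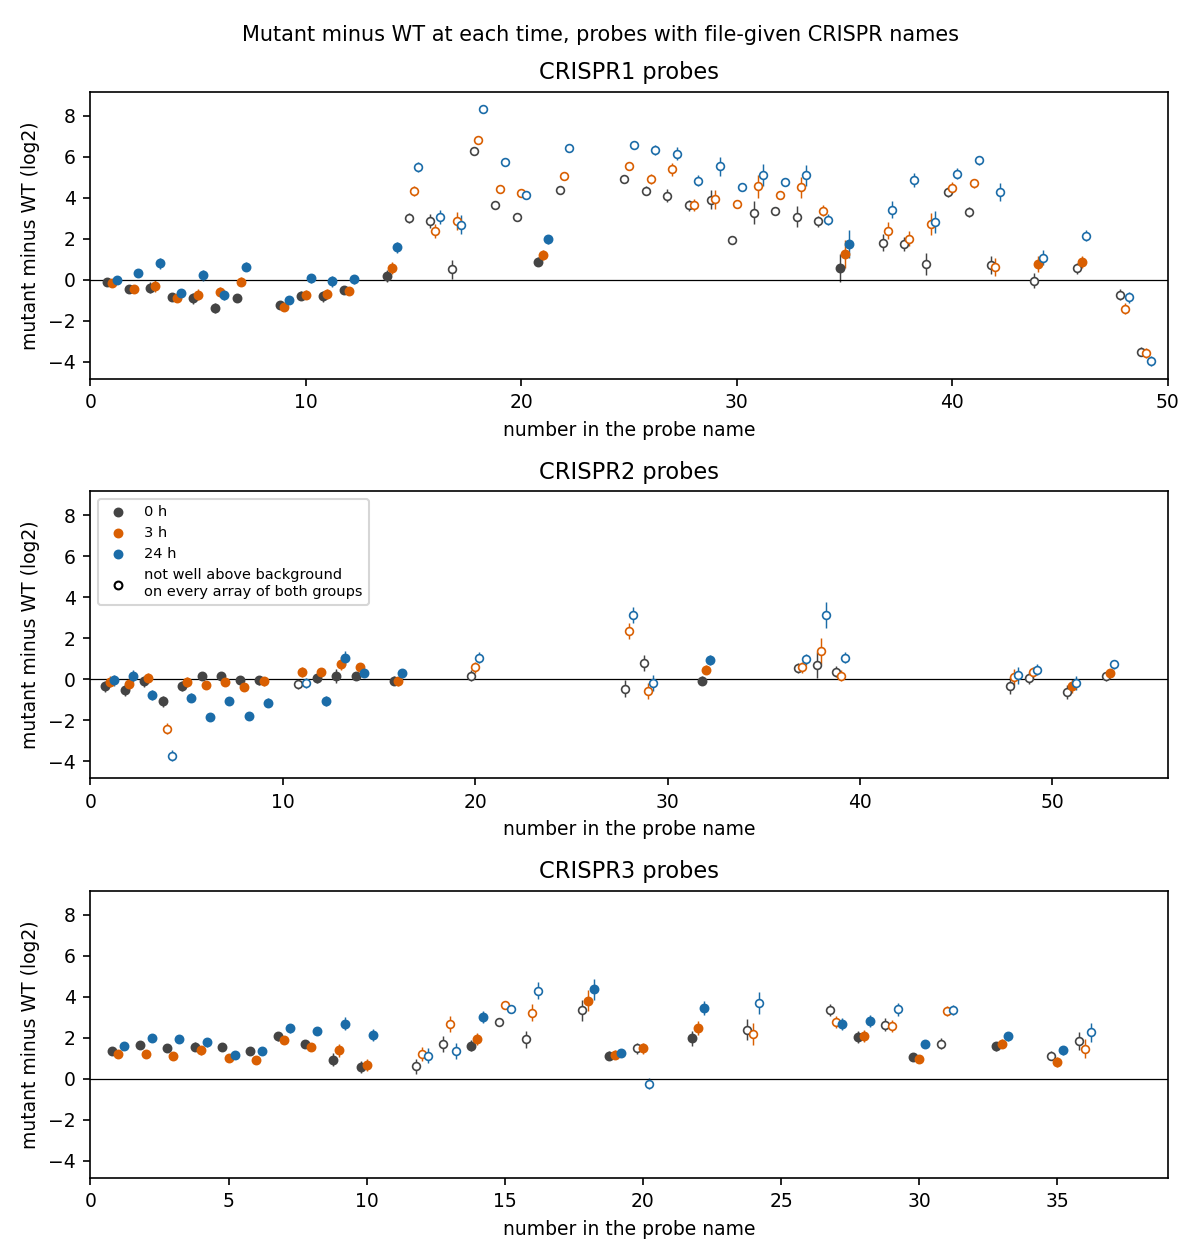
Difference between the mutant and WT (log2, y axis) of the tested probes used here against the number in its name (x axis), for CRISPR1, CRISPR2 and CRISPR3, at 0 h, 3 h and 24 h; points are fitted differences, bars their standard errors, and open points are probes not detected on every array of both groups. Where a group is undetected the plotted difference is set against background: R_CRISPR1-18 at 24 h, plotted at 8.32, was at least 63.8-fold higher, and R_CRISPR1-49 at 24 h, plotted at -3.97, at least 3.12-fold lower.

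CRISPR3 was higher in the mutant throughout. Of its 29 tested probes, 25 were higher at 0 h, 28 at 3 h and 28 at 24 h, and none was lower. Leaving out calls on probes that no array of either group detected, 22, 28 and 26 were higher. The median log2 difference was 1.61 at 0 h, 1.51 at 3 h and 2.25 at 24 h, or 1.36, 1.37 and 1.97 with undetected signals at the detection limit. In the deposited value table, which gave the smallest medians, they were 0.91, 0.60 and 0.62. CRISPR2 was not called as a series at any time, with medians of -0.03, 0.11 and 0.15 over 25 probes, but at 24 h its members went both ways, 8 higher and 8 lower. Of the 11 tested probes numbered 1 to 12, 8 were lower in the mutant at 24 h, with a median of -1.06, against 1 at 0 h and 1 at 3 h. Of the 14 tested probes numbered 13 to 55, 8 were higher at 24 h, with a median of 0.82. An array of either group detected each of these 8. Most of this stretch was dim, with 4 of its 43 probes detected on all WT arrays and 4 on all mutant arrays. The floor also differed: undetected R_CRISPR2-19 had a scaled log2 mean of -3.29 in the mutant and -4.09 in WT at 24 h. Background alone can thus give a like difference, so this median is not read as higher expression. R_CRISPR2-4 was detected on both mutant arrays at 0 h and on neither at 3 h or 24 h, and was at least 2.68-fold lower than in WT at 24 h (limma, adjusted p = 1.36e-05) and at least 1.25-fold lower at 3 h (adjusted p = 0.00033). All 4 LEADER1 probes were higher in the mutant at 24 h, with a median of 0.99. Of the 2 tested LEADER2 probes, 1 was lower at 24 h, with a median of -0.84 over both.

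As sets, CRISPR1 and CRISPR3 stood above the other probes at each time with the preset correlation of 0.01 between probes (camera, adjusted p = 2.16e-05, 4.56e-09 and 6.45e-10 for CRISPR1, and 7.64e-15, 5.67e-20 and 1.53e-13 for CRISPR3). Averaged over the times the medians were 2.05 for CRISPR1 and 1.78 for CRISPR3, with adjusted p = 4.23e-08 and 3.91e-18. None of these calls held with a correlation estimated from the data. The adjusted p was then 0.475, 0.232 and 0.201 for CRISPR1, and 0.19, 0.105 and 0.201 for CRISPR3, at 0 h, 3 h and 24 h. Averaged over the times it was 0.275 and 0.128 with an estimated correlation. LEADER1 at 24 h had an adjusted p = 0.0103, and 0.229 with an estimated correlation. CRISPR1 also lost its direction where only its 15 probes detected on all 12 arrays were kept, since this leaves out nearly all of the probes numbered 15 to 42: the median was then -0.51 at 0 h, -0.56 at 3 h and 0.07 at 24 h. The 5 series were chosen after the data were seen, because the files name no other probes.

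Among the probes with serial names, the largest differences averaged over the times were of the same on or off kind. SYN-CR-76-21075 and SYN-CR-76-14443 were detected on 6 of 6 WT arrays and 0 of 6 mutant arrays. SYN-CR-76-21075 was at least 3.57-fold lower in the mutant at 0 h, 64.4-fold at 3 h and 59.6-fold at 24 h (limma, adjusted p = 8.07e-06, 1.64e-07 and 2.35e-07). SYN-CR-76-14443 was at least 2.65-fold, 42.8-fold and 38.7-fold lower (adjusted p = 1.42e-05, 2.19e-07 and 3.11e-07). SYN-CR-76-11994 and SYN-CR-76-59842 were detected on 6 of 6 mutant arrays and 0 of 6 WT arrays. SYN-CR-76-11994 was at least 31.5-fold higher at 0 h, 38.2-fold at 3 h and 9.43-fold at 24 h (adjusted p = 1.09e-05, 7.67e-06 and 4.73e-05). SYN-CR-76-59842 was at least 24.7-fold, 32.4-fold and 19-fold higher (adjusted p = 2.61e-06, 2.12e-06 and 3.59e-06). Whether a probe lies in the deleted gene is not known from the files, so the deletion itself was not checked here.

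**Figure D2:**
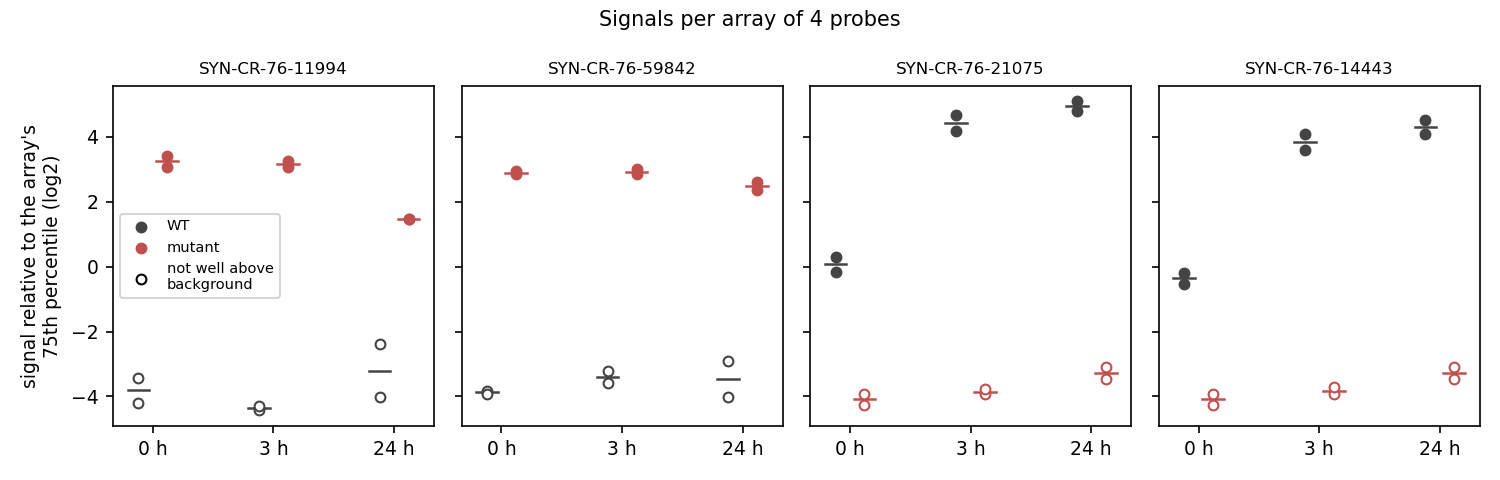
Signal of each array (log2 relative to the array's 75th percentile, y axis) at 0 h, 3 h and 24 h (x axis) for the 4 serially named probes with the largest average differences between the genotypes; lines are means of 2 arrays and open points are signals not well above background. The WT mean of SYN-CR-76-21075 was 0.08 at 0 h, 4.43 at 3 h and 4.94 at 24 h.

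Over the whole array, 64 probes were detected on all 6 mutant arrays and on none of the WT arrays, and 138 the other way round. The mutant arrays detected fewer probes on average, so these 2 counts cannot be set against each other. Averaged over the times, 52 of the 64 were higher in the mutant by at least 3 on the log2 scale. Only 5 of the 138 were lower by as much. Of the 64, 15 were CRISPR1 probes and 3 were CRISPR3 probes. This is more than their share of the 18066 probes detected on all mutant arrays, 71 of which were CRISPR probes (Fisher's exact test, two-sided, p = 1.51e-29; neighbouring probes of a series are not independent). Of the 138, 2 were CRISPR1 probes, among 24816 probes detected on all WT arrays, 48 of which were CRISPR probes (Fisher's exact test, two-sided, p = 0.0293). These 2, R_CRISPR1-48 and R_CRISPR1-49, have neighbouring numbers and are not independent, so no enrichment is concluded from this p-value.

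Across all tested probes, 12601 differed between the genotypes at 0 h (5458 higher and 7143 lower in the mutant), 8779 at 3 h (3711 and 5068) and 21513 at 24 h (9686 and 11827). Leaving out probes that no array of either group detected, the counts were 12041, 8328 and 20374. With a log2 difference of at least 1 as well, the full counts were 7029, 4961 and 13367. Averaged over the 3 times, 21326 probes differed (9068 higher and 12258 lower), and 6266 of them by at least 1. The CRISPR and leader probes made up 46 of the 1149 probes called higher at all 3 times, where independent lists would share 145, and 4 of the 1192 called lower at all 3 times, where independent lists would share 316.5. Leaving out an array of the time compared, after which its group keeps 1 array, lowered the count at each time, in proportion most at 3 h.

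The balance of higher and lower calls was not settled by the data, because it moved with the scaling of the arrays and with the filter on dim probes. Scaled on the median, the calls were 7271 higher and 4872 lower at 0 h, 14618 and 7716 at 24 h, and 13531 and 8176 on average. With the 75th percentile taken over probes detected on all arrays, they were 3818 and 9456 at 0 h, 6388 and 15283 at 24 h, and 5885 and 16130 on average. In the deposited value table they were 6078 and 2216 at 0 h, 1593 and 4691 at 3 h, 2374 and 17831 at 24 h, and 3635 and 11779 on average. Normexp background correction gave 11531 and 9020 at 24 h, and 11285 and 9816 on average. In the main scaling, the probes detected on all 12 arrays gave 3899 higher and 3062 lower at 0 h, 3040 and 2456 at 3 h, 7150 and 4103 at 24 h, and 6635 and 4198 on average. Without a filter, the calls were 24637 and 12401 at 24 h, and 22919 and 13283 on average. The median of all probes at 24 h was -0.07 in the main scaling, 0.34 with the median and -0.38 with the percentile over detected probes. CRISPR1 15 to 42 and CRISPR3 lay above these medians at each time. Both genotypes of a time shared a slide. On the slide of 0 h and 24 h, WT arrays filled 1 row and mutant arrays the other, so row and genotype cannot be told apart at these times.

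**Figure D3:**
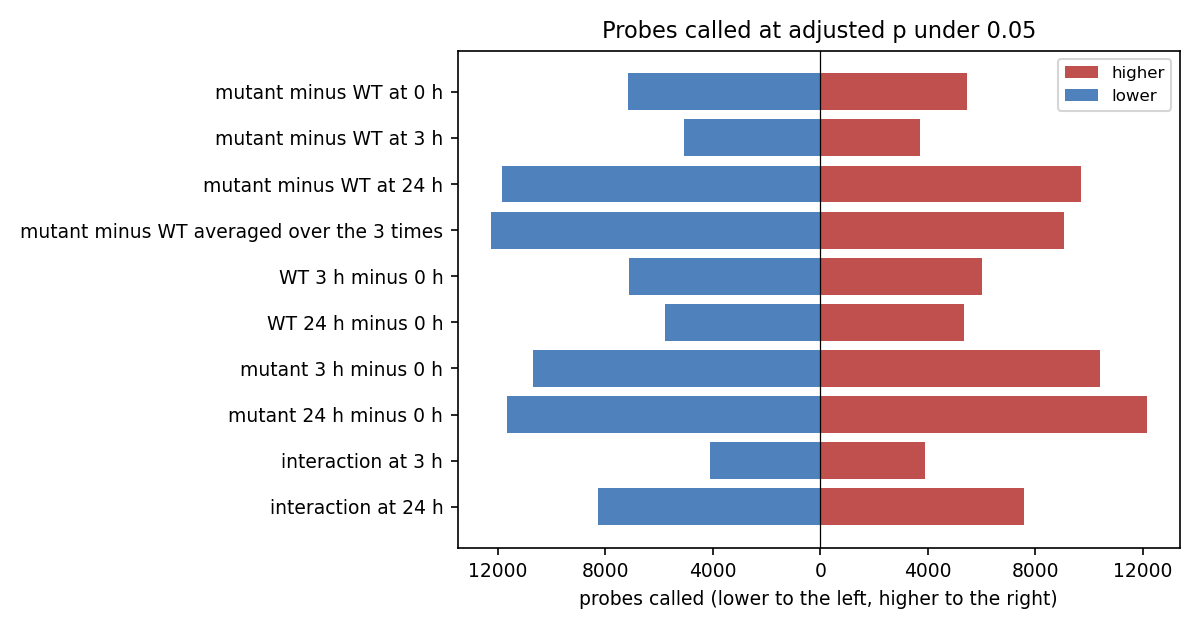
Number of probes called at adjusted p under 0.05 (x axis) in each of the 10 comparisons (y axis), higher to the right and lower to the left. The mutant minus WT count was 21513 at 24 h, against 12601 at 0 h and 8779 at 3 h; the split into higher and lower moves with the scaling and the filter.

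The WT time course asks how expression moved after the change of carbon supply, with which, by the labels, the buffer pH changed too. The first CRISPR2 probes were lower at 3 h than at 0 h in WT: 10 of the 11 tested probes numbered 1 to 12 fell, with a median log2 change of -1.84. Of the 14 tested probes numbered 13 to 55, 1 was higher and 1 lower. These bounds were also set after the values were seen. R_CRISPR2-4 changed by -2.61 ± 0.27 (SE), R_CRISPR2-12 by -2.23 ± 0.23 and R_CRISPR2-8 by -1.92 ± 0.14 (limma, adjusted p = 5.64e-05, 5.66e-05 and 5.04e-06, 2 arrays against 2). Both tested LEADER2 probes fell, with a median of -1.31. At 24 h the same 11 CRISPR2 probes had a median of -0.24 against 0 h, and 3 of them were lower. Of the 13 tested CRISPR1 probes numbered 1 to 14, 10 rose from 0 h to 24 h, with a median of 0.79; the median at 3 h was 0.20. CRISPR1 as a series was not called at 24 h, with a median of -0.03 and 29 of 42 probes not called. R_CRISPR1-12 rose by 1.19 ± 0.22 (adjusted p = 0.00259) and R_CRISPR1-49 by 1.25 ± 0.24 (adjusted p = 0.00335) at 24 h. Of the 4 LEADER1 probes, 3 fell at 24 h, R_LEADER1-2 by a change of -0.93 ± 0.16 and R_LEADER1-1 by -0.89 ± 0.17 (adjusted p = 0.00209 and 0.00319), and R_LEADER2-3 had a change of -1.17 ± 0.18 (adjusted p = 0.00106). Of the 29 tested CRISPR3 probes, 2 were higher at 3 h and 10 at 24 h, or 1 and 9 among those detected on an array of either group. The detected one at 3 h was R_CRISPR3-3, with a change of 0.66 ± 0.15 (adjusted p = 0.00729). At 24 h, R_CRISPR3-27 was at least 1.23-fold higher (adjusted p = 0.00203). Further along CRISPR2, R_CRISPR2-29, undetected at 0 h, was at least 1.74-fold higher at 3 h (adjusted p = 0.00267).

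As sets, CRISPR2 at 3 h and CRISPR3 and LEADER1 at 24 h passed the test in WT with the preset correlation (camera, adjusted p = 0.0192, 0.0104 and 0.0134). None passed with an estimated correlation (adjusted p = 0.814, 0.576 and 0.373). The serial probes SYN-CR-76-21075 and SYN-CR-76-14443, absent from the mutant arrays, rose in WT by log2 changes of 4.35 ± 0.25 and 4.19 ± 0.25 at 3 h and of 4.86 ± 0.25 and 4.67 ± 0.25 at 24 h (limma, adjusted p = 1.38e-06, 1.86e-06, 1.03e-06 and 1.41e-06). Over all probes, 13122 changed in WT at 3 h (6017 higher, 7105 lower) and 11106 at 24 h (5336 higher, 5770 lower), with changes from -7.26 to 10.71 at 3 h and from -7.04 to 10.56 at 24 h. The deposited value table gave a median of 0.31 for the whole of CRISPR2 at 3 h, where the main scaling gave -0.55, and of -0.71 for its probes 1 to 12. All 3 h arrays lay on 1 slide with its own scan and all 0 h and 24 h arrays on the other, so slide and time cannot be told apart for 3 h against 0 h. The splits at 3 h were 7841 and 5475 with the percentile over detected probes and 22203 and 2125 in the deposited value table, which also gave 9722 and 2594 at 24 h.

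In the mutant, the first CRISPR2 probes fell at 3 h and stayed low at 24 h. Of the 11 numbered 1 to 12, 10 fell at 3 h, with a median of -1.73, and 8 were lower than at 0 h at 24 h, with a median of -1.24. R_CRISPR2-4 was at least 3.57-fold lower at 3 h and 2.32-fold lower at 24 h (limma, adjusted p = 2.41e-06 and 4.47e-06). R_CRISPR2-8 changed by -2.29 ± 0.14 at 3 h and by -2.02 ± 0.14 at 24 h (adjusted p = 1.07e-06 and 2.32e-06), and R_LEADER2-3 by -2.02 ± 0.18 and -1.86 ± 0.18 (adjusted p = 1.36e-05 and 2.07e-05). CRISPR1 rose at 24 h in 34 of its 42 tested probes and CRISPR3 in 22 of its 29, with medians of 1.43 and 1.07 (camera, adjusted p = 1.3e-07 and 0.000111, and 0.372 for both with an estimated correlation). Over all probes, 21085 changed at 3 h (10396 higher, 10689 lower) and 23785 at 24 h (12149 higher, 11636 lower). Of the 23785, 1672 were probes that no mutant array of 0 h or 24 h detected, 1449 of them higher, since the scanner's floor lay higher relative to the 75th percentile on the dim arrays of 24 h. The splits were 13973 and 8154 at 3 h with the percentile over detected probes. In the deposited value table they were 10654 and 5613 at 3 h and 3788 and 13906 at 24 h. At 24 h they were 7803 and 4880 among probes detected on all 12 arrays and 28506 and 12051 without a filter.

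The interaction asks whether the change from 0 h differed between the genotypes. At 24 h the first CRISPR2 probes fell further in the mutant than in WT: 6 of 11 passed this test, with a median of -1.07, or -0.66 with undetected signals at the detection limit, among them R_CRISPR2-6 and R_CRISPR2-8, which all arrays compared detected. In CRISPR1, 24 of 42 probes passed this test upward at 24 h and 1 downward, with a median of 1.30 (camera, adjusted p = 4.92e-07, and 0.389 with an estimated correlation). Of the 24, 17 were numbered 15 to 42. No WT array of 0 h or 24 h detected 20 of the 25 tested probes of that stretch, so their WT change was not measured, and their median of 1.99 was 1.39 with undetected signals at the detection limit. Of the 13 numbered 1 to 14, all detected on every array, 6 passed upward and 1 downward, with a median of 0.73, or 0.41 with normexp background correction and -0.13 in the deposited value table. All 4 LEADER1 probes differed at 24 h, with a median of 1.055 (camera, adjusted p = 0.0158, and 0.389 with an estimated correlation). At 3 h, 6 of 42 CRISPR1 probes and 1 of 11 CRISPR2 probes numbered 1 to 12 passed the test. Over all probes, 7979 differed in their change at 3 h (3897 higher, 4082 lower) and 15856 at 24 h (7579 higher, 8277 lower). The count at 3 h was 4799 without replicate 2 of the mutant at 3 h and 4758 without replicate 1 of WT at 3 h. The splits at 3 h were 2803 and 4534 with the median, 4636 and 2997 with the percentile over detected probes and 693 and 5794 in the deposited value table. At 24 h they were 8984 and 6518 with the median and 1092 and 16713 in the deposited value table, 5514 and 3809 among probes detected on all 12 arrays, and 21939 and 8683 without a filter.

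The changes of the genotypes resembled each other more at 3 h than at 24 h. Across 36778 probes, which are not independent replicates, the WT and mutant changes from 0 h correlated with r = 0.729 (rho = 0.702) at 3 h and r = 0.542 (rho = 0.489) at 24 h. They share no array, but at 3 h both contain the same difference between slides. Formed from single arrays, the correlations ranged from 0.593 to 0.735 at 3 h and from 0.389 to 0.603 at 24 h. At 3 h, 4669 probes rose in both genotypes, where independent lists would share 1701, and 5385 fell in both, where independent lists would share 2065. At 24 h these counts were 3541 against 1763 and 4049 against 1826. Opposite calls were found for 363 probes at 3 h and 1022 at 24 h, where independent lists would give 3757 and 3594.

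**Figure D4:**
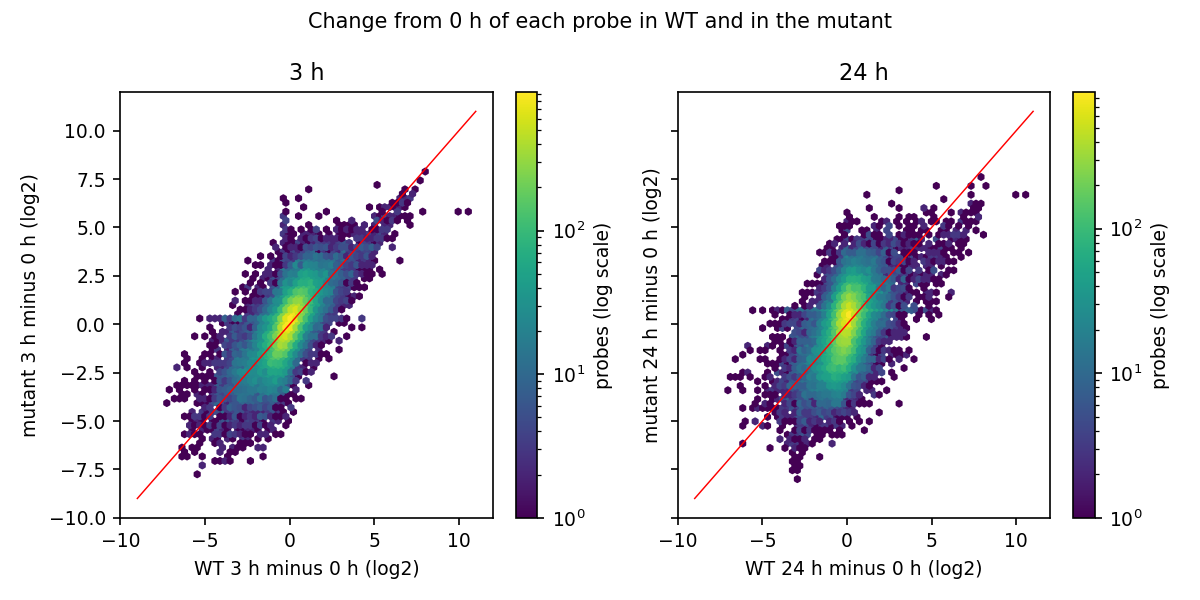
Change from 0 h (log2) in the mutant (y axis) against WT (x axis) for the 36778 tested probes at 3 h and 24 h; colour gives the number of probes on a log scale and the red line marks equal changes. The correlation across probes was 0.729 at 3 h and 0.542 at 24 h.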

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

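All tests of explanations in this part were chosen after the results were seen. Changes from 0 h differed between the genotypes, by the interaction term of the limma fit, for 7979 probes at 3 h and for 15856 at 24 h. The CRISPR1 series differed by a median of 0.45 at 3 h and 1.30 at 24 h, CRISPR3 by 0.52 and LEADER1 by 1.055 at 24 h (log2, mutant change minus WT change). With an estimated correlation between probes these series calls were lost, with adjusted p = 0.914 and 0.389 for CRISPR1, 0.508 for CRISPR3 and 0.389 for LEADER1. The deposited value table turned the sign of CRISPR1 at 3 h and of CRISPR3 at 24 h. At 3 h, single probes differed by 2.79 for R_CRISPR2-28, 2.36 for R_CRISPR1-17 and -1.32 for R_CRISPR2-4. No array of these groups detected R_CRISPR2-28 and 1 detected R_CRISPR1-17, so their values are differences between background signals, and R_CRISPR2-4 was undetected in the mutant at 3 h. At 24 h the differences were 3.59 for R_CRISPR2-28, 3.57 for R_CRISPR1-42, 3.13 for R_CRISPR1-38, -2.65 for R_CRISPR2-4, -1.99 for R_CRISPR2-6 and -1.78 for R_CRISPR2-8. Of these, R_CRISPR2-28, R_CRISPR1-42 and R_CRISPR1-38 were detected in the mutant at 24 h alone, where they were at least 3.26-fold, 3.85-fold and 5.79-fold higher than in the mutant at 0 h, and R_CRISPR2-4 was undetected in the mutant at 24 h, so their sizes rest on background signals. Serial probes SYN-CR-76-21075 and SYN-CR-76-14443 differed by -4.12 and -3.92 at 3 h and by -4.06 and -3.87 at 24 h, being undetected in the mutant. SYN-CR-76-11994 differed by -2.38 at 24 h, being undetected in WT.

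CRISPR1 probes numbered 15 to 42 were bright in the mutant and near background in WT. Dimmer WT arrays cannot account for this, since the WT arrays detected a larger share of probes, by 8.07 percentage points on average. More transcription of all of CRISPR1 by a like amount in the mutant is argued against at 0 h and 3 h. Averaged over the times, the probes numbered 1 to 14 had a median difference of -0.48 and none reached 1. None was called higher at 0 h or 3 h. At 24 h their median was 0.01, with 3 higher, 4 lower and a highest difference of 1.56. Over the whole series at 24 h, 29 of the 42 tested probes were higher and 6 lower, with quartiles of 0.23 and 5.09. A rise of all probes by a like amount is thus argued against at 24 h too, while an uneven rise stays open there. The bounds were set after the values were seen, so the contrast between the stretches follows from that choice and adds no support. A stretch missing from the CRISPR1 locus of the WT strain, or present in the mutant's strain of origin alone, stays open as a strain difference unrelated to SbtB: 2 of the 28 probes were detected on all 6 WT arrays, which may reflect binding of other RNA or a stretch that is not wholly absent. An effect of SbtB on how far CRISPR1 is transcribed was not tested and also stays open, and RNA signals alone cannot separate a missing stretch from one that is not transcribed.

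SYN-CR-76-21075, SYN-CR-76-14443 and 1 more serial probe were detected on all WT arrays and on no mutant array. Among the probes with this pattern, they had the largest falls in the average over the times. Dimmer mutant arrays are argued against at 3 h and 24 h, since of other probes as bright in WT both mutant arrays detected 100% and 99.8%. At 0 h both mutant arrays detected 80.6% of such probes and neither detected 8.91%, so dimmer arrays stay open there. That the probes report 1 transcript that the mutant lacks stays open too: their WT changes from 0 h to 3 h lay within 0.23 of each other on the log2 scale, but probes chosen for large falls may be alike for that reason alone. Whether they lie in the deleted gene could not be tested, as the files give no gene for them. If they do, their rise after 0 h bears on the conflict in the carbon labels, since sbtB is known to be induced at low CO2, but the data alone leave that conflict open.

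The genotypes differed in more probes at 24 h (21513) than at 0 h (12601) or 3 h (8779). The dim mutant arrays of 24 h are argued against as the whole cause: among the 17384 probes detected on all 12 arrays, the share called at 24 h was 1.79 times the larger of the shares at 0 h and 3 h. An effect of the slide row that adds equally at 0 h and 24 h would cancel in the interaction, which still called 15856 probes. With the percentile taken over detected probes, the calls at 24 h were 1.63 times those at 0 h, so this scaling did not remove the excess. Among the probes detected on all 12 arrays, the median absolute log2 difference was 0.628 at 24 h, 0.381 at 0 h and 0.322 at 3 h. The measured difference was thus larger at 24 h, but its cause was not tested. An effect of the loss of SbtB and a difference in growth or RNA quality between the cultures both stay open.

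For the count of 21326 probes averaged over the times, 100 of the 108 possible splits within the times were drawn, and the real one was the 1 split with as many calls, so a chance division of the arrays is argued against, to the resolution that 100 splits allow. The highest other split called 17399. It exchanged the genotypes at 0 h alone, and so carries the genotype difference of the later times.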

How the results depend on the processing

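All alternatives here were planned except the 75th percentile over detected probes and the counts limited to probes detected in the groups compared, which were chosen after seeing the data. Of 265 counts under an alternative, 237 stayed within 1.5 times. Those that did not are given in the order mutant minus WT at 0 h, 3 h, 24 h and on average, WT at 3 h and 24 h, mutant at 3 h and 24 h, and interaction at 3 h and 24 h. Among probes detected on all 12 arrays, where fewer probes are tested, all 10 moved: 6961, 5496, 11253, 10833, 6823, 6167, 10255, 12683, 4655 and 9323. With a log2 change of at least 1, the first 7 were 7029, 4961, 13367, 6266, 7837, 6553 and 14049. Without a filter, 37038 were called for the mutant minus WT at 24 h, 36202 on average, 40557 for the mutant at 24 h and 30622 for the interaction at 24 h, where many added probes lie at the floor. The deposited value table gave 8294 for the mutant minus WT at 0 h and 24328 for WT at 3 h (the cause was not tested). Only the arrays compared gave 6932 for the mutant minus WT at 0 h, with fewer arrays to estimate the spread. Leaving out each array, where the lone array left is assumed to vary like the others, gave 3479 to 9994 for the mutant minus WT at 3 h and 4758 to 8856 for the interaction at 3 h.

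The labels do not say that equal replicate numbers mark a shared culture or day. The deviations of same-numbered arrays correlated at 0.38 at 0 h, 0.26 at 3 h and 0.15 at 24 h between the genotypes, and from -0.38 to 0.34 between times of a genotype. With a replicate block within each time, the mutant minus WT counts were 14523, 10930 and 22870, and no count moved by over 1.5 times. The correlations of the WT and mutant changes were 0.674 at 3 h and 0.474 at 24 h without a filter, and otherwise moved by less than the spread between single arrays.

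The averages of CRISPR1 (2.05) and CRISPR3 (1.78) over the times lost their call with an estimated correlation between probes. Where only probes detected on all 12 arrays were kept, which leaves 15 of 42 CRISPR1 probes, the CRISPR1 medians of the mutant minus WT turned to -0.51 at 0 h, -0.56 at 3 h and -0.35 on average. The deposited value table turned CRISPR2 in WT at 3 h to 0.31, and the interactions of CRISPR1 at 3 h to -0.085 and of CRISPR3 at 24 h to -0.24. That it subtracts no background spot by spot and compresses dim probes was seen, but the cause was not tested. Over the series, 1181 values kept their call, 58 lost it and 30 gained one. Of the named probes, 1102 values kept their call, 33 lost it and 0 reversed. Choosing the brightest probe per gene was not run, since no gene is known. Signal over background limits the mutant at 24 h most, where 34.0% and 39.4% of probes were detected.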
